A study of Mus musculus with 12 samples.

How the data were processed

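RNA was sequenced in 12 libraries, 8 of mixed cultures (WT, Kdm5a knockout, Rb1 knockout, DKO) and 4 of purified myotubes (WT, DKO), n = 2 per group. The values are the signal the authors deposited for each gene and library, a count of reads divided by a size factor for the library. Dividing every column by its smallest step gave whole reads, with 100% of values within 0.01 of a whole number, and the factors equal those of the median-of-ratios method over the 12 libraries. Upstream steps follow the submitters' processing notes: reads were aligned with TopHat 1.2.0 to mm9 and counts were normalised with DESeq, whose version is not given in the sources used here, nor are the read counter and the annotation release. Normalised values were analysed as deposited, and the recovered whole reads served for read totals, counting intervals and alternative tests. No column was left without a sample. Gene names, chromosomes, exonic lengths and shared exons came from GENCODE M21, an annotation of a later assembly than mm9, so no coordinates are given. Of 36229 identifiers 30983 (85.5%) had a symbol there, and those without held at most 2.83% of the reads of a library.

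Depth in recovered reads was 16458373 and 18469731 for WT mixed, 21567550 and 27688963 for Kdm5a knockout, 11983750 and 17864184 for Rb1 knockout, 31158818 and 41309134 for DKO mixed, 9549351 and 14116839 for WT purified and 8688604 and 15570731 for DKO purified. The mitochondrial ribosomal gene mt-Rnr2 held 10.0 to 16.6% of reads in ribosome-depleted libraries and at most 0.109% in oligo(dT) libraries. Between replicates, squared differences were 3.91 to 6.85 times counting error, and 74.2 times for DKO purified. Median absolute log2 differences between replicates were 0.107 to 0.176, and 0.499 for DKO purified.

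Each comparison used limma with an intensity trend on log2(value + 1), over genes with a mean value of at least 10 in the libraries fitted, two-sided, with Benjamini-Hochberg adjustment over those genes and a threshold of 0.05 on the adjusted p. The 8 mixed libraries shared a fit (17199 genes), the 4 purified libraries had their own (16670 genes), and the difference of the DKO effect between library types was fitted on all 12 (17273 genes). With n = 2 per group, the spread is shared across groups and moderated across genes. A gene is said to rise or fall only where it passed.

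Gene lists were fixed before the data were examined, as were the tests and most of the other settings tried. The 32 lists covered nuclear-encoded oxidative phosphorylation, mitochondrial ribosomal proteins, tricarboxylic acid cycle, fatty acid oxidation, mitochondrial biogenesis and dynamics, mitochondrial import and folding, sarcomere, myogenic regulators and fusion, excitation-contraction coupling and neuromuscular junction, muscle energy metabolism, glycolysis, DNA replication and G1/S E2F targets, G2/M and mitosis, p53 targets and cell-cycle inhibitors, fibroblast matrix, smooth muscle, adipocyte, cartilage and bone, macrophage and blood, endothelium, neural and glia, epithelium, interferon-stimulated genes, inflammatory cytokines, replication-dependent histones, KDM5 family with pocket proteins and E2F factors, endoplasmic reticulum stress and heat shock, autophagy and lysosome, cholesterol synthesis, cytosolic ribosomal proteins, mitochondrially encoded messengers and sex-linked genes. A list with at least 5 measured members was tested with limma's camera, which asks whether its genes move more than other genes, at a preset correlation of 0.01 between genes, and again with an estimated correlation, each adjusted over the lists of a comparison. The fry test, which asks whether a list's genes move on balance in a direction, was run beside it. Lists passing camera, then camera with an estimated correlation, numbered 7 and 0 for Kdm5a knockout against WT, 23 and 5 for Rb1 knockout against WT, 21 and 7 for DKO against WT, 13 and 3 for DKO against Rb1 knockout, 20 and 12 for DKO against Kdm5a knockout, 13 and 3 for the interaction, 7 and 0 for purified DKO against WT and 14 and 0 for the difference between library types.

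Genes were named by a rule fixed at the same time. It took Rb1 (ENSMUSG00000022105), Kdm5a (ENSMUSG00000030180), Kdm5b (ENSMUSG00000042207), Kdm5c (ENSMUSG00000025332), Myod1 (ENSMUSG00000009471), Myog (ENSMUSG00000026459), Ckm (ENSMUSG00000030399), Myh3 (ENSMUSG00000020908) and Ppargc1a (ENSMUSG00000029167) everywhere. It added the 6 (or 4) genes with the largest rise and fall in a comparison among those that passed, whose libraries did not overlap between groups and whose higher group mean was at least 100, leaving out clone names. From each list described it added up to 4 members with the smallest p. Genes whose exons overlap another gene in the reference are named as uncertain, because the same reads may be counted for both.

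A gene without reads in a group is given as at least N-fold higher or lower, with 3 reads set as the floor over the group, and a gene with 1 to 3 reads as a ratio with a 95% interval. These floors and intervals cover counting error only, not the spread between libraries. Simulated libraries had 200 genes changed on purpose and the spread measured between replicates. In the mixed fit 69% of 2-fold and 97% of 4-fold changes were recovered, with 8.29% of calls false. In the purified fit 2% and 44% were recovered, with 11.5% false. The adjusted threshold depends on how many genes change. The comparisons called far more than 200 genes, so these rates do not carry over to them. Counts shared between comparisons are given beside the number expected if the calls were independent, and where libraries are shared the correlation and covariance across genes are given beside those of 20 random draws that keep only those libraries in common.

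Other settings tried were a pseudocount of 0.5 or 5, no filter, a filter of 50, TMM scaling, edgeR and DESeq2 on the recovered reads, only the 4 libraries compared, a replicate block, and each library left out in turn. Removal of genes with overlapping annotation and of genes on X and Y was added after values had been seen. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.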

Results

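Embryonic fibroblasts of C57BL/6 mice were turned toward skeletal muscle with an adenovirus carrying MyoD, the transcription factor that starts the muscle programme. Virus was left on the cells for 24 h in medium with 2% horse serum and 10 µg/ml insulin, and culture went on for 72 h in fresh medium. The cells were wild type (WT), lacked Kdm5a (a histone demethylase that binds the retinoblastoma protein), lacked Rb1 (the retinoblastoma protein, a repressor of E2F factors) or lacked both (DKO). The question the labels state is how loss of either gene, alone or together, changes expression in fibroblasts driven to form myotubes. Each genotype had n = 2 libraries of the mixed culture, made from 1.7 µg of RNA depleted of ribosomal RNA and read for 40 bases. WT and DKO also had n = 2 libraries each of myotubes separated from the mixed culture by size, left 24 h to recover and selected with oligo(dT), from 1.5 µg of RNA, 15 PCR cycles and reads of 36 bases. The labels do not say that 2 libraries of a group came from separate cultures or embryos, so every p-value below measures only the spread between these libraries. Changes are log2 differences of the normalised value + 1 (± standard error), a scale that understates changes of genes with few reads, medians of lists are of log2 changes, and levels are means ± SD of normalised counts. Counts of list members that rose or fell are over all genes tested, and those adjusted over the list alone follow, rises then falls, where they differ and are otherwise the same.

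The targeted genes stood as follows in each library. Kdm5a read 1637 and 1871 in the WT libraries, 1088 and 1192 in the Kdm5a knockouts, 2094 and 1886 in the Rb1 knockouts and 1319 and 1369.7 in the DKO. In purified myotubes it read 3032 and 2775 in WT and 787 and 614 in DKO. Kdm5a fell in the Kdm5a knockout (-0.62 ± 0.08, limma adjusted p = 0.000189, n = 2), in the mixed DKO (-0.38 ± 0.08, adjusted p = 0.00146) and in the purified DKO (-2.06 ± 0.21, adjusted p = 0.00287), and its change in the Rb1 knockout did not pass (0.18 ± 0.08, adjusted p = 0.0680). The last passed as a rise without WT mixed replicate 2 (0.28, adjusted p = 0.0174) or Rb1 KO mixed replicate 2 (0.26, adjusted p = 0.0413). Kdm5a shares exons with Ccdc77 in the reference, so its level is uncertain. Rb1 read 5616 and 5649.5 in WT, 5079 and 5193 in the Kdm5a knockouts, 4457 and 4448 in the Rb1 knockouts, 5309 and 5662 in the DKO, 3499.5 and 3218 in purified WT and 2356 and 2104 in purified DKO. Rb1 fell in the Rb1 knockout (-0.34 ± 0.05, limma adjusted p = 5.31e-05), and did not pass in the mixed DKO (-0.04 ± 0.05, adjusted p = 0.510), the Kdm5a knockout (-0.13 ± 0.05, adjusted p = 0.0692) or the purified DKO (-0.59 ± 0.19, adjusted p = 0.0580). In purified DKO against WT, Rb1 passed as a fall without DKO purified replicate 1 (-0.67, adjusted p = 0.00299) or DKO purified replicate 2 (-0.51, adjusted p = 0.00643). Rb1 shares exons with Rcbtb2 and Lpar6, and the labels do not say which part of either gene was removed, so the whole-gene level cannot check the Rb1 label and the groups are named as labelled. Kdm5b, a paralogue of Kdm5a, did not pass in the Kdm5a knockout (0.11 ± 0.08, adjusted p = 0.330) and fell in the Rb1 knockout (-0.84 ± 0.08), the mixed DKO (-1.25 ± 0.08) and the purified DKO (-2.64 ± 0.20).

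Sex-linked genes split the mixed libraries by Kdm5a genotype. Xist, the RNA of the inactive X chromosome, whose exons overlap its antisense gene Tsix, averaged 0 in WT and 0 in the Rb1 knockout, against 3181 ± 100.1 in the Kdm5a knockout and 6871 ± 86.8 in the DKO. Ddx3y, on the Y chromosome, averaged 3313 ± 8.02 in WT and 1173 ± 132 in the Rb1 knockout and had no reads in the Kdm5a knockout or the DKO. The same held in purified myotubes, where Xist averaged 2.17 ± 0.441 in WT and 9571 ± 438 in DKO. Comparisons of Kdm5a knockout with WT, DKO with WT and DKO with Rb1 knockout therefore also compare female with male cells, whereas Rb1 knockout against WT and DKO against Kdm5a knockout lie within a sex. The comparisons of female with male cells, and purified DKO with WT, carry that difference in every result below. Differences between embryos or cell lines were not tested and may enter every comparison, including those within a sex.

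**Figure D1:**
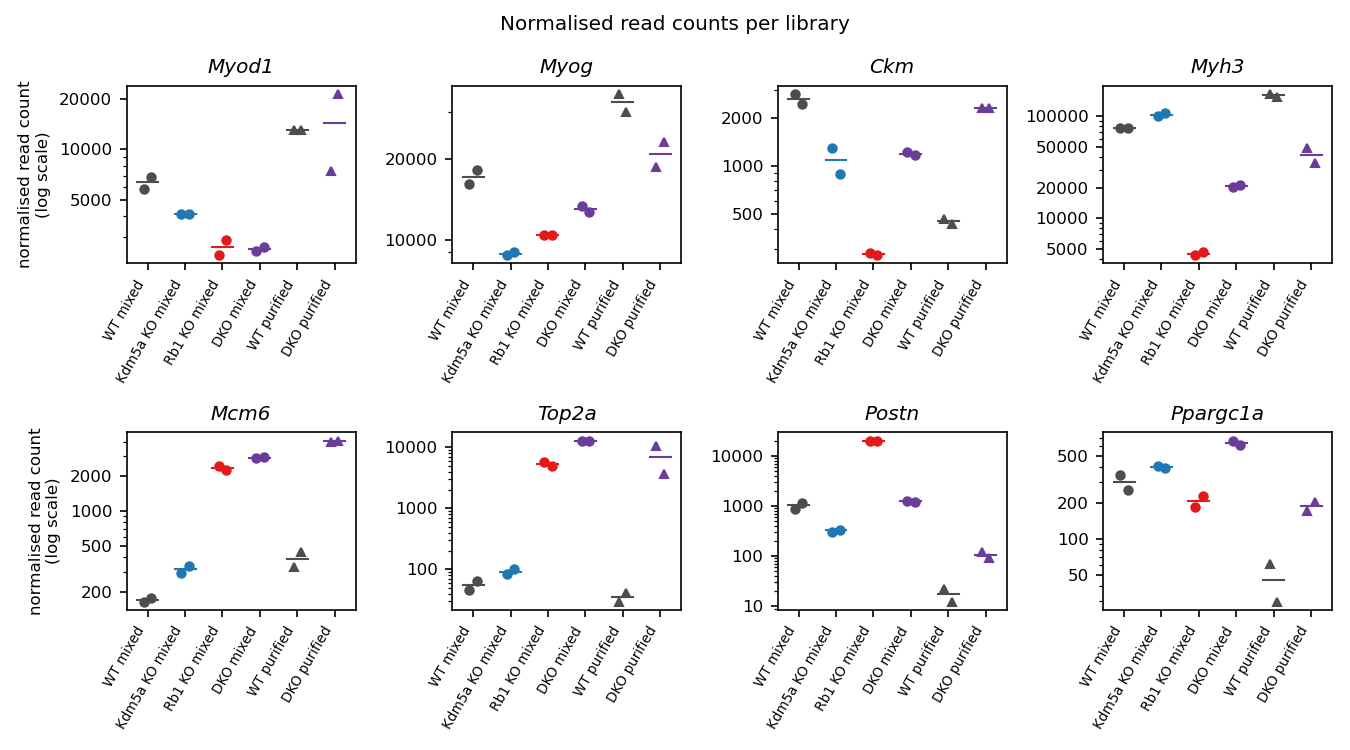
Normalised counts of 8 genes in each of the 12 libraries. Points are libraries and bars are group means.

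In Rb1 knockout cultures the muscle programme was low. Embryonic myosin heavy chain Myh3 fell from 76998 ± 122 in WT to 4531 ± 207 (-4.09 ± 0.05, limma adjusted p = 2.75e-14, n = 2), creatine kinase Ckm fell (-3.24 ± 0.14, sharing exons with A930016O22Rik, so its level is uncertain here and below), and the regulators Myod1 (-1.28 ± 0.09) and Myog (-0.73 ± 0.06) fell less. Myod1 counts cannot separate the cell's own transcript from the vector's. Of 44 measured sarcomere and contractile genes, 0 rose, 43 fell and 1 did not pass (median -3.10, camera adjusted p = 2.67e-22, adjusted p = 0.0375 with an estimated correlation), among them the slow troponin Tnni1 (-3.91 ± 0.05) and Myh8 (-9.14 ± 0.22). Excitation-contraction coupling and neuromuscular junction genes fell as a group, and of 30 measured 1 rose, 27 fell and 2 did not pass (median -2.78, camera adjusted p = 8.02e-12, adjusted p = 0.0338 with an estimated correlation), as did muscle energy metabolism genes, of which 1 rose, 22 fell and 1 did not pass among 24 (median -2.34, camera adjusted p = 9.56e-10, adjusted p = 0.0338 with an estimated correlation). Examples were the junction kinase Musk (-5.67 ± 0.09), the acetylcholine receptor subunit Chrnd (-3.12 ± 0.07), the glycogen phosphorylase Pygm (-3.23 ± 0.05) and the glycogen-targeting subunit Ppp1r3a (-5.32 ± 0.10). Mstn, which restrains muscle growth, fell from 5912 ± 1594 to 9.25 ± 0.284 (-9.15 ± 0.20). Myogenic regulators and fusion genes were split, and of 24 measured 8 rose, 12 fell and 4 did not pass (median -0.42, camera adjusted p = 0.0445, adjusted p = 0.108 with an estimated correlation), with Mef2c falling (-3.56 ± 0.06). That list did not pass without genes on X and Y (camera adjusted p = 0.0817), where its median was -0.36.

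Cell-cycle genes rose in the same Rb1 knockout cultures. Of 68 DNA replication and G1/S E2F targets measured 66 rose, 0 fell and 2 did not pass (median 3.11, camera adjusted p = 1.15e-21, adjusted p = 0.0338 with an estimated correlation), such as the helicase subunit Mcm6 (3.77 ± 0.09) and the methyltransferase Ezh2 (3.23 ± 0.09). Of 72 G2/M and mitosis genes 70 rose and 2 fell (median 4.51, camera adjusted p = 2.23e-20, adjusted p = 0.0401 with an estimated correlation), such as Ccnf (4.25 ± 0.10) and the condensin subunit Ncapg2 (3.06 ± 0.08). The mitotic gene Ube2c went down, from 17933.8 and 17502.9 in WT to 2024.1 and 1745.9. The contractile gene Tnnc2 had similar values (18992.6 and 18540.1, then 1720.3 and 1477.1), so the level of Ube2c is uncertain here and below. Replication-dependent histones and p53 targets and cell-cycle inhibitors also shifted upward. Of 32 histone genes, 25 rose, 4 fell and 3 did not pass (26 and 4 adjusted over the list alone, median 2.61, camera adjusted p = 0.000141, adjusted p = 0.0877 with an estimated correlation). Of 31 p53 targets and inhibitors, 21 rose, 8 fell and 2 did not pass (median 1.07, camera adjusted p = 0.00222, adjusted p = 0.0878 with an estimated correlation). Mdm2 rose (2.46 ± 0.07) and Apaf1 rose (2.26 ± 0.07), whereas the inhibitor Cdkn1c fell (-2.82 ± 0.04). In the list of KDM5 family, pocket proteins and E2F factors, 12 rose, 7 fell and 4 did not pass of 23 (12 and 8 adjusted over the list alone, median 0.38, camera adjusted p = 0.195), with the pocket protein Rbl1 rising (2.73 ± 0.11) and Kdm5b (-0.84 ± 0.08) and Kdm5c (-0.66 ± 0.06) falling.

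Mitochondrial and metabolic genes fell with Rb1 loss. Of 78 nuclear-encoded oxidative phosphorylation subunits measured 5 rose, 62 fell and 11 did not pass (median -0.95, camera adjusted p = 2.56e-11, adjusted p = 0.0525 with an estimated correlation), such as Ndufa9 of complex I (-1.97 ± 0.07) and the ATP synthase subunit Atp5b (-1.66 ± 0.04). Tricarboxylic acid cycle genes, fatty acid oxidation genes and mitochondrial ribosomal proteins moved the same way. Of 22 tricarboxylic acid cycle genes, 4 rose and 18 fell (median -1.11, camera adjusted p = 4.21e-06, adjusted p = 0.0932 with an estimated correlation). Of 24 fatty acid oxidation genes, 4 rose, 16 fell and 4 did not pass (median -0.90, camera adjusted p = 0.00222, adjusted p = 0.0603 with an estimated correlation). Of 77 mitochondrial ribosomal genes, 7 rose, 44 fell and 26 did not pass (median -0.47, camera adjusted p = 0.000398, adjusted p = 0.0520 with an estimated correlation). Sucla2 fell (-1.70 ± 0.06) and the acyl-CoA dehydrogenase Acadm fell (-3.09 ± 0.17). Glycolysis genes and cholesterol synthesis genes fell too, for instance Hk2 (-2.14 ± 0.08) and Dhcr7 (-2.11 ± 0.08). Of 21 glycolysis genes, 1 rose, 16 fell and 4 did not pass (median -0.98, camera adjusted p = 1.52e-05, adjusted p = 0.0520 with an estimated correlation). Of 19 cholesterol synthesis genes, 1 rose, 16 fell and 2 did not pass (median -1.49, camera adjusted p = 4.53e-06, adjusted p = 0.0815 with an estimated correlation). Ppargc1a, a coactivator of mitochondrial genes, fell (-0.54 ± 0.15, limma adjusted p = 0.00728), while the list of mitochondrial biogenesis and dynamics regulators was mixed. Of 25 biogenesis and dynamics genes, 10 rose, 12 fell and 3 did not pass (median -0.16, camera adjusted p = 0.607). Without WT mixed replicate 1 (adjusted p = 0.0792) or Rb1 KO mixed replicate 1 (adjusted p = 0.0747) Ppargc1a did not pass. Lower medians were also measured for mitochondrial protein import and folding, autophagy and lysosome, cytosolic ribosomal proteins and mitochondrially encoded messengers. Of 19 import and folding genes, 2 rose, 12 fell and 5 did not pass (median -0.64, camera adjusted p = 0.00514, adjusted p = 0.0877 with an estimated correlation). Of 30 autophagy and lysosome genes, 3 rose, 21 fell and 6 did not pass (median -0.51, camera adjusted p = 0.000109, adjusted p = 0.0520 with an estimated correlation). Of 75 ribosomal protein genes, 4 rose, 32 fell and 39 did not pass (4 and 31 adjusted over the list alone, median -0.37, camera adjusted p = 0.00419, adjusted p = 0.108 with an estimated correlation). Of 7 mitochondrially encoded messengers, 1 rose, 5 fell and 1 did not pass (1 and 6 adjusted over the list alone, median -0.24, camera adjusted p = 0.0458, adjusted p = 0.409 with an estimated correlation). The last did not pass without WT mixed replicate 1 (camera adjusted p = 0.0796) or Rb1 KO mixed replicate 2 (camera adjusted p = 0.0651). The endoplasmic reticulum stress and heat shock list did not pass, although the small heat shock protein Hspb8 fell (-2.58 ± 0.07). Of 26 stress genes, 9 rose, 10 fell and 7 did not pass (median 0.13, camera adjusted p = 0.343, the camera test pointing down against the median).

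Fibroblast matrix and interferon genes rose in Rb1 knockout cultures. Of 47 fibroblast extracellular matrix genes measured 45 rose and 2 fell (median 2.65, camera adjusted p = 9.95e-15, adjusted p = 0.0932 with an estimated correlation), with periostin Postn rising from 1022 ± 192 to 19907 ± 263 (4.29 ± 0.10) and Col5a2 rising (2.55 ± 0.06). Interferon-stimulated genes and inflammatory cytokines and acute response genes rose as groups, such as Tap1 (4.78 ± 0.20) and Cxcl12 (4.02 ± 0.20). Of 40 interferon-stimulated genes, 36 rose, 2 fell and 2 did not pass (median 2.71, camera adjusted p = 3.74e-08, adjusted p = 0.0603 with an estimated correlation). Of 18 inflammatory genes, 14 rose, 1 fell and 3 did not pass (median 2.85, camera adjusted p = 5.63e-05, adjusted p = 0.0520 with an estimated correlation). Lists of other cell types were read as a check on composition. Smooth muscle and myofibroblast genes and cartilage and bone genes passed, with Notch3 (4.26 ± 0.15) and Matn3 (5.04 ± 0.32) rising. Of 17 smooth muscle genes, 13 rose, 3 fell and 1 did not pass (median 1.89, camera adjusted p = 0.00248, adjusted p = 0.108 with an estimated correlation). Of 11 cartilage and bone genes, 7 rose, 1 fell and 3 did not pass (median 1.75, camera adjusted p = 0.0121, adjusted p = 0.0932 with an estimated correlation). The cartilage and bone list did not pass without genes that share exons (camera adjusted p = 0.0532). Adipocyte, macrophage and blood, endothelium, neural and glia and epithelium lists did not pass. Of 14 adipocyte genes, 3 rose, 7 fell and 4 did not pass (median -0.48, camera adjusted p = 0.141). Of 13 macrophage and blood genes, 9 rose, 2 fell and 2 did not pass (median 1.80, camera adjusted p = 0.205). Of 12 endothelial genes, 8 rose, 3 fell and 1 did not pass (median 1.98, camera adjusted p = 0.141). Of 13 neural genes, 5 rose, 3 fell and 5 did not pass (median -0.05, camera adjusted p = 0.837, the camera test pointing up against the median). Of 7 epithelial genes, 1 rose, 3 fell and 3 did not pass (median -1.23, camera adjusted p = 0.310). In all, 12237 of 17199 genes passed for Rb1 knockout against WT, 6336 rising and 5901 falling, and 6944 of them changed at least 2-fold. Among the largest rises were the E2F factor E2f7 (8.01 ± 0.58), Crabp1 (754 ± 68.6 against 1.73 ± 0.938, ratio 440, 95% counting interval 150 to 2136) and Cdca7l (no reads in WT, at least 240.0-fold higher, but sharing exons with Dnah11), and among the largest falls Cpne4 (-7.20 ± 0.66) and Crym (-6.95 ± 0.38).

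**Figure D2:**
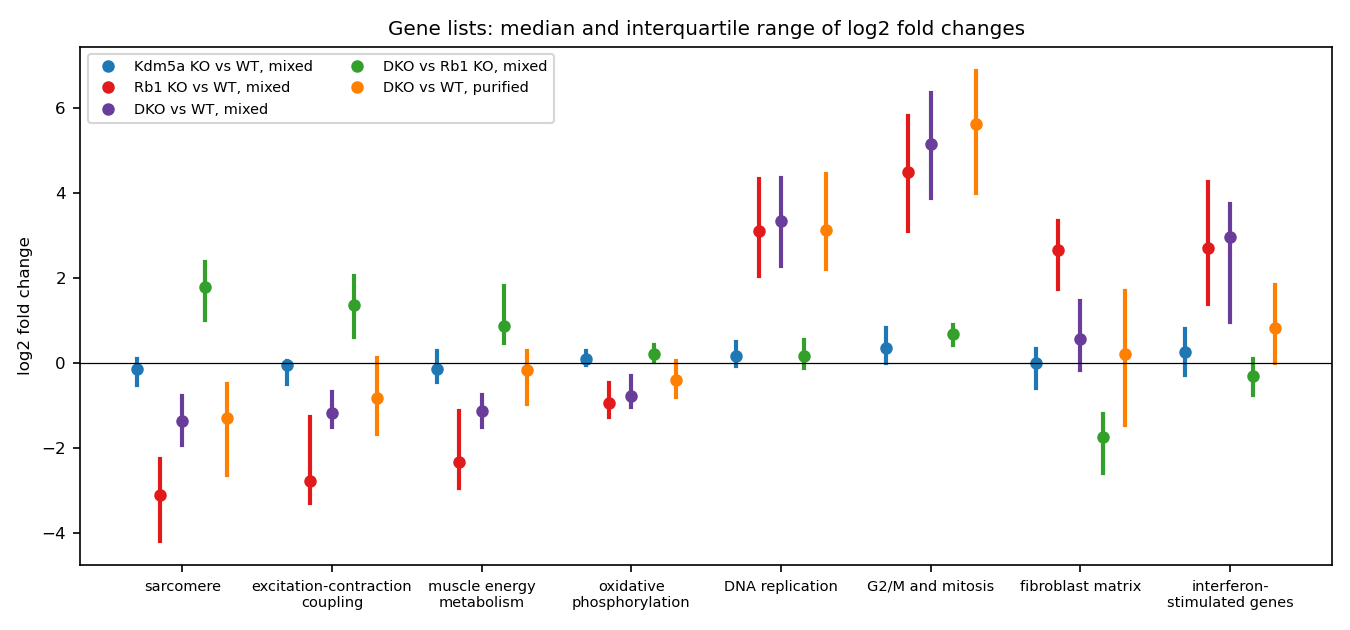
Median log2 change and interquartile range of each gene list in 5 comparisons. Each list contributes its measured members only.

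Against the Rb1 knockout, DKO cultures had muscle genes at higher levels and matrix genes at lower levels. Myh3 rose from 4531 ± 207 to 20800.4 ± 570.1 (2.20 ± 0.05, limma adjusted p = 1.39e-11, n = 2), Ckm rose (2.09 ± 0.14) and Ppargc1a rose from 206 ± 29.8 to 641 ± 38.6 (1.64 ± 0.15). Myog rose less (0.33 ± 0.06) and Myod1 did not pass (-0.03 ± 0.09, adjusted p = 0.804). Of 44 sarcomere genes measured 40 rose, 0 fell and 4 did not pass (median 1.79, camera adjusted p = 1.49e-26, adjusted p = 0.0362 with an estimated correlation), among them Lmod2 (4.12 ± 0.08) and Neb (3.16 ± 0.06, sharing exons with Gm13522 and uncertain). Coupling and junction genes and muscle energy genes rose as well, such as the calcium pump inhibitor Sln (18.5 ± 4.397 to 1136 ± 3.62, 5.88 ± 0.18), Musk (2.71 ± 0.09) and Ppp1r3a (4.37 ± 0.10). Of 30 coupling and junction genes, 24 rose, 3 fell and 3 did not pass (25 and 4 adjusted over the list alone, median 1.36, camera adjusted p = 3.64e-11, adjusted p = 0.0362 with an estimated correlation). Of 24 muscle energy genes, 18 rose, 1 fell and 5 did not pass (19 and 1 adjusted over the list alone, median 0.88, camera adjusted p = 1.78e-09, adjusted p = 0.0362 with an estimated correlation). Smaller upward shifts were measured for oxidative phosphorylation subunits, the tricarboxylic acid cycle and mitochondrially encoded messengers, for instance Ndufb9 (0.74 ± 0.06), Sucla2 (0.73 ± 0.06) and mt-Cytb (0.60 ± 0.05). Of 78 oxidative phosphorylation genes, 31 rose, 4 fell and 43 did not pass (median 0.21, camera adjusted p = 0.000353, adjusted p = 0.236 with an estimated correlation). Of 22 tricarboxylic acid cycle genes, 14 rose, 1 fell and 7 did not pass (15 and 1 adjusted over the list alone, median 0.27, camera adjusted p = 0.00242, adjusted p = 0.262 with an estimated correlation). Of 7 mitochondrially encoded messengers, 7 rose and 0 fell (median 0.73, camera adjusted p = 1.8e-05, adjusted p = 0.236 with an estimated correlation). Fatty acid oxidation genes did not pass as a list, although the fatty acid transporter Cd36 rose (3.98 ± 0.22) and Cpt1a fell (-1.96 ± 0.13). Of 24 fatty acid oxidation genes, 9 rose, 3 fell and 12 did not pass (median 0.21, camera adjusted p = 0.153). The orphan receptor Esrrg rose (3.60 ± 0.15) within a biogenesis list that did not pass. Of 25 biogenesis and dynamics genes, 9 rose, 5 fell and 11 did not pass (median 0.07, camera adjusted p = 0.324).

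Matrix genes went the other way between DKO and Rb1 knockout. Of 47 measured 0 rose, 43 fell and 4 did not pass (0 and 44 adjusted over the list alone, median -1.74, camera adjusted p = 1.08e-24, adjusted p = 0.129 with an estimated correlation), with Postn (-4.01 ± 0.10), Thbs1 (-4.45 ± 0.10) and Col12a1 (-3.74 ± 0.10) falling. Inflammatory genes, smooth muscle and myofibroblast genes and stress genes fell, such as Csf1 (-2.26 ± 0.10), Ptgs2 (-1.81 ± 0.09) and Asns (-1.29 ± 0.10). Of 18 inflammatory genes, 1 rose, 13 fell and 4 did not pass (1 and 14 adjusted over the list alone, median -1.56, camera adjusted p = 9.8e-05, adjusted p = 0.0843 with an estimated correlation). Of 17 smooth muscle genes, 3 rose, 11 fell and 3 did not pass (median -1.29, camera adjusted p = 0.000236, adjusted p = 0.152 with an estimated correlation). Of 26 stress genes, 2 rose, 16 fell and 8 did not pass (median -0.40, camera adjusted p = 0.000463, adjusted p = 0.0843 with an estimated correlation). Cell-cycle genes did not return toward WT and G2/M genes stood higher still, as did DNA replication genes by less, such as Dlgap5 (2.15 ± 0.23) and Rad51ap1 (1.07 ± 0.08). Of 72 G2/M genes, 39 rose, 1 fell and 32 did not pass (40 and 1 adjusted over the list alone, median 0.69, camera adjusted p = 2.22e-07, adjusted p = 0.152 with an estimated correlation). Of 68 replication genes, 23 rose, 7 fell and 38 did not pass (22 and 7 adjusted over the list alone, median 0.17, camera adjusted p = 0.0394, adjusted p = 0.262 with an estimated correlation). The replication list did not pass without Rb1 KO mixed replicate 2 (camera adjusted p = 0.0854), DKO mixed replicate 2 (camera adjusted p = 0.0541) or genes that share exons (camera adjusted p = 0.0884). Across all genes 8128 of 17199 passed, 3965 rising and 4163 falling. Among the largest changes beside the sex-linked genes were rises of Sln, given above, of Cox6a2 (5.42 ± 0.17, sharing exons with Itgad and uncertain), Casq1 (4.69 ± 0.51) and Pde1c (4.64 ± 0.12) and falls of Rprl3 (-9.49 ± 0.42) and Ifi202b (no reads in DKO, at least 429-fold lower). DKO cells were female and Rb1 knockout cells male, so every change given here follows sex as well as genotype.

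Many genes differed between DKO and Rb1 knockout in the direction opposite to their change with Rb1 loss. Of 5901 genes that fell in Rb1 knockout against WT, 2526 rose in DKO against Rb1 knockout, where 1360 would be shared if the calls were independent, and 831 fell further, where 1428 would. Of 6336 genes that rose with Rb1 loss, 2439 fell, where 1534 would be shared if independent, and 746 rose further, where 1461 would. Myh3 and Postn were in these sets. The Rb1 knockout libraries enter both comparisons with opposite sign, which by itself produces opposite changes, so part of each excess can come from those shared libraries. Across all genes the correlation of these changes was -0.45, against -0.50 in draws with only the shared libraries in common. The -0.50 follows from the shared group whatever the size of the spread, so that comparison decides nothing. The covariance was -0.71 against -0.04, so spread between replicate libraries gives little of it. Anything particular to the Rb1 knockout cells as a group would still enter both comparisons. Genes are not independent replicates in either value.

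**Figure D3:**
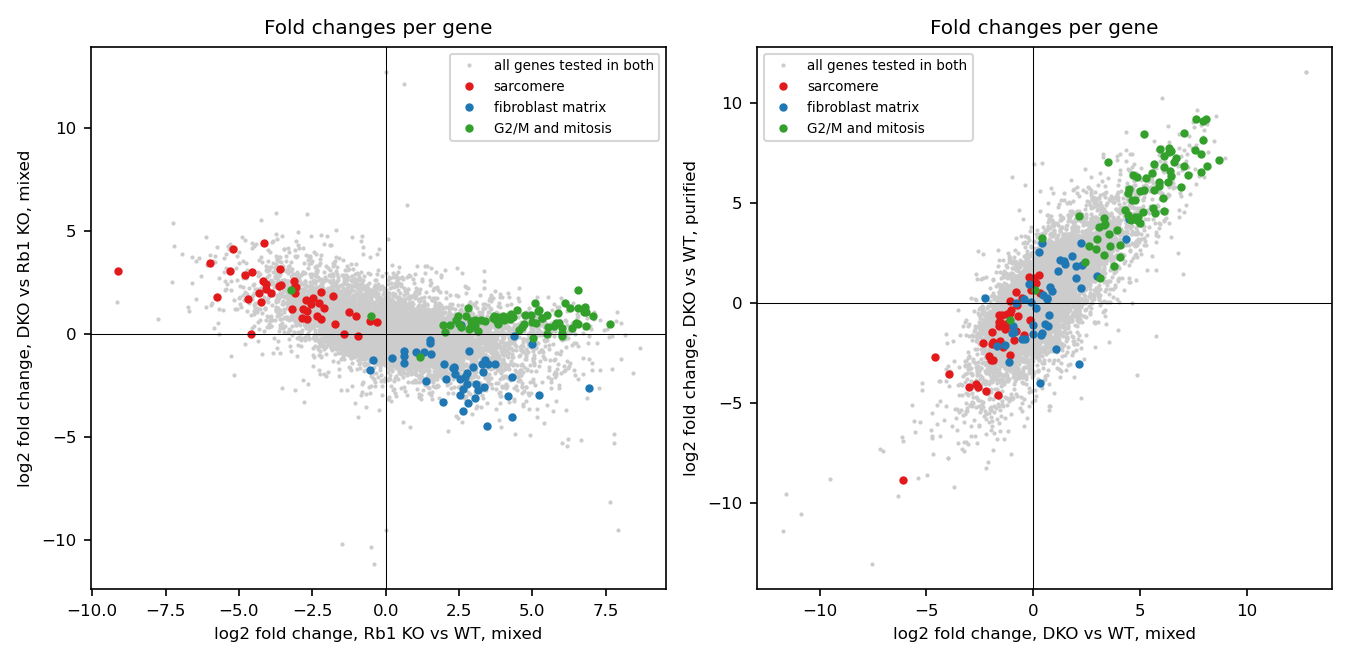
Log2 changes of genes in pairs of comparisons. Sarcomere, fibroblast matrix and G2/M genes are coloured.

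Compared with WT, DKO cultures still had lower muscle genes and higher cell-cycle genes. Myh3 fell from 76998 ± 122 to 20800.4 ± 570.1 (-1.89 ± 0.05, limma adjusted p = 1.56e-11, n = 2), Ckm (-1.15 ± 0.14), Myod1 (-1.31 ± 0.09) and Myog (-0.40 ± 0.06) fell, and Ppargc1a rose (1.10 ± 0.15). Of 44 sarcomere genes 0 rose, 38 fell and 6 did not pass (median -1.38, camera adjusted p = 3.79e-13, adjusted p = 0.0510 with an estimated correlation), such as Tnnt2 (-1.94 ± 0.05) and Tnni1 (-1.93 ± 0.05). Replication genes and G2/M genes rose, such as Rrm1 (3.62 ± 0.08), Smc4 (3.60 ± 0.08), Dlgap5 (8.70 ± 0.23) and E2f7 (8.53 ± 0.58). Of 68 replication genes, 68 rose and 0 fell (median 3.34, camera adjusted p = 1.13e-26, adjusted p = 0.0276 with an estimated correlation). Of 72 G2/M genes, 70 rose, 1 fell and 1 did not pass (median 5.16, camera adjusted p = 4.59e-26, adjusted p = 0.0472 with an estimated correlation). Glycolysis, oxidative phosphorylation, autophagy and lysosome and stress genes fell, for instance the cathepsin Ctsd (-1.34 ± 0.05). Of 21 glycolysis genes, 1 rose, 17 fell and 3 did not pass (median -1.12, camera adjusted p = 9.69e-07, adjusted p = 0.0472 with an estimated correlation). Of 78 oxidative phosphorylation genes, 3 rose, 59 fell and 16 did not pass (4 and 60 adjusted over the list alone, median -0.77, camera adjusted p = 3.32e-09, adjusted p = 0.0561 with an estimated correlation). Of 30 autophagy and lysosome genes, 2 rose, 24 fell and 4 did not pass (median -0.66, camera adjusted p = 1.09e-05, adjusted p = 0.0472 with an estimated correlation). Of 26 stress genes, 2 rose, 20 fell and 4 did not pass (median -0.51, camera adjusted p = 0.000103, adjusted p = 0.0472 with an estimated correlation). Interferon-stimulated and endothelial genes rose, such as Plvap (4.81 ± 0.28) and Erg (4.21 ± 0.31), and matrix genes were divided, with Sparc falling (-1.71 ± 0.05). Of 40 interferon-stimulated genes, 35 rose, 2 fell and 3 did not pass (37 and 3 adjusted over the list alone, median 2.96, camera adjusted p = 1.67e-08, adjusted p = 0.0538 with an estimated correlation). Of 12 endothelial genes, 10 rose, 0 fell and 2 did not pass (11 and 0 adjusted over the list alone, median 2.46, camera adjusted p = 0.00210, adjusted p = 0.0565 with an estimated correlation). Of 47 matrix genes, 28 rose, 11 fell and 8 did not pass (median 0.57, camera adjusted p = 0.0240, adjusted p = 0.550 with an estimated correlation). Without WT mixed replicate 1 the matrix list did not pass (camera adjusted p = 0.0652), nor did it without genes that share exons (camera adjusted p = 0.109). In all 11681 of 17199 genes passed (5847 rose, 5834 fell).

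Fewer genes differed between Kdm5a knockout and WT. Against WT, Myog fell from 17189.7 ± 1503 to 8858 ± 156 (-0.95 ± 0.06, limma adjusted p = 3.83e-07, n = 2), Myod1 fell (-0.62 ± 0.09) and Ckm fell (-1.30 ± 0.14), whereas Myh3 rose (0.42 ± 0.05) and Ppargc1a did not pass (0.42 ± 0.15, adjusted p = 0.0581). Ppargc1a passed as a rise without WT mixed replicate 1 (0.64, adjusted p = 0.0112). Kdm5c, on the X chromosome, rose (0.29 ± 0.06). Of 44 sarcomere genes 7 rose, 21 fell and 16 did not pass (median -0.15, camera adjusted p = 0.0130, adjusted p = 0.418 with an estimated correlation), with Acta1 falling (-0.91 ± 0.10) and Actn3 rising (0.65 ± 0.05). Myogenic regulators and coupling and junction genes leaned down, such as Srf (-0.96 ± 0.10) and Musk (-1.41 ± 0.09). Of 24 myogenic regulators, 3 rose, 13 fell and 8 did not pass (3 and 16 adjusted over the list alone, median -0.30, camera adjusted p = 0.00144, adjusted p = 0.391 with an estimated correlation). Of 30 coupling and junction genes, 0 rose, 10 fell and 20 did not pass (1 and 10 adjusted over the list alone, median -0.05, camera adjusted p = 0.0181, adjusted p = 0.418 with an estimated correlation). G2/M genes, replication genes and mitochondrially encoded messengers leaned up, such as Cenpf (2.17 ± 0.13), Mcm6 (0.87 ± 0.09) and Asf1b (1.31 ± 0.10). Of 72 G2/M genes, 25 rose, 2 fell and 45 did not pass (27 and 3 adjusted over the list alone, median 0.36, camera adjusted p = 0.00144, adjusted p = 0.418 with an estimated correlation). Of 68 replication genes, 21 rose, 4 fell and 43 did not pass (median 0.17, camera adjusted p = 0.0316, adjusted p = 0.418 with an estimated correlation). Of 7 mitochondrially encoded messengers, 5 rose, 0 fell and 2 did not pass (median 0.20, camera adjusted p = 0.0148, adjusted p = 0.435 with an estimated correlation). Nuclear-encoded oxidative phosphorylation, glycolysis and matrix genes did not pass as lists, although Pdk1 rose (1.39 ± 0.16), Timp1 rose (2.23 ± 0.15) and Postn fell (-1.64 ± 0.10). Of 78 oxidative phosphorylation genes, 13 rose, 3 fell and 62 did not pass (11 and 3 adjusted over the list alone, median 0.10, camera adjusted p = 0.0608). Of 21 glycolysis genes, 10 rose, 3 fell and 8 did not pass (median 0.27, camera adjusted p = 0.0598). Without WT mixed replicate 1 the oxidative phosphorylation list passed (camera adjusted p = 0.0286). The glycolysis list passed without WT mixed replicate 1 (camera adjusted p = 0.0286), Kdm5a KO mixed replicate 2 (camera adjusted p = 0.0467), DKO mixed replicate 1 (camera adjusted p = 0.0471), DKO mixed replicate 2 (camera adjusted p = 0.0470) or genes that share exons (camera adjusted p = 0.0145). Of 47 matrix genes, 11 rose, 18 fell and 18 did not pass (14 and 18 adjusted over the list alone, median 0.00, camera adjusted p = 0.406, the camera test pointing down against the median).

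Sex-linked genes were the largest changes of Kdm5a knockout against WT. Of 6 measured 2 rose and 4 fell (camera adjusted p = 0.0463, adjusted p = 0.435 with an estimated correlation), Xist being at least 1881-fold higher and Ddx3y at least 2799-fold lower. The sex-linked list did not pass without WT mixed replicate 1 (camera adjusted p = 0.0772), WT mixed replicate 2 (camera adjusted p = 0.101), Rb1 KO mixed replicate 1 (camera adjusted p = 0.109) or Rb1 KO mixed replicate 2 (camera adjusted p = 0.110). Autosomal genes with large changes included Barx1 (6.08 ± 0.77) and Srgn (4.24 ± 0.42), which rose, and Evx2 (-5.75 ± 0.51) and Dlk1 (-5.26 ± 0.72), which fell. In all 4685 of 17199 genes passed (2308 rose, 2377 fell) and 1239 changed at least 2-fold. The count was 3057 without Kdm5a KO mixed replicate 1, and no list passed with an estimated correlation. Without WT mixed replicate 2 the replication list (camera adjusted p = 0.0803) and the mitochondrially encoded list (camera adjusted p = 0.0803) did not pass, nor did the coupling and junction list without WT mixed replicate 1 (camera adjusted p = 0.0693) or the replication list without Kdm5a KO mixed replicate 2 (camera adjusted p = 0.0607). The replication list also did not pass without Rb1 KO mixed replicate 1 (camera adjusted p = 0.0502), Rb1 KO mixed replicate 2 (camera adjusted p = 0.0501) or genes that share exons (camera adjusted p = 0.0501), nor did the sarcomere list without genes that share exons (camera adjusted p = 0.164).

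On the Kdm5a-null background, muscle genes were again lower and cell-cycle genes higher without Rb1. Between DKO and Kdm5a knockout Myh3 fell (-2.31 ± 0.05, limma adjusted p = 4.3e-12, n = 2) and Myod1 fell (-0.69 ± 0.09), Myog rose (0.56 ± 0.06), Ppargc1a rose (0.68 ± 0.15) and Ckm did not pass (0.16 ± 0.14, adjusted p = 0.340). Ckm passed as a rise without Kdm5a KO mixed replicate 1 (0.43, adjusted p = 0.00540). Of 44 sarcomere genes 3 rose, 35 fell and 6 did not pass (median -1.05, camera adjusted p = 2.31e-11, adjusted p = 0.0481 with an estimated correlation), of 68 replication genes 67 rose, 0 fell and 1 did not pass (median 3.11, camera adjusted p = 1.98e-25, adjusted p = 0.0303 with an estimated correlation) and of 72 G2/M genes 70 rose and 2 fell (median 4.82, camera adjusted p = 7.3e-25, adjusted p = 0.0426 with an estimated correlation). Mki67 (8.01 ± 0.43) rose and Mstn (-6.89 ± 0.20) fell. Oxidative phosphorylation and glycolysis genes fell, and p53 targets rose. Of 78 oxidative phosphorylation genes, 2 rose, 63 fell and 13 did not pass (2 and 65 adjusted over the list alone, median -0.84, camera adjusted p = 1.99e-11, adjusted p = 0.0481 with an estimated correlation). Of 21 glycolysis genes, 0 rose, 18 fell and 3 did not pass (1 and 19 adjusted over the list alone, median -1.38, camera adjusted p = 1.4e-07, adjusted p = 0.0426 with an estimated correlation). Of 31 p53 targets and inhibitors, 23 rose, 4 fell and 4 did not pass (median 1.14, camera adjusted p = 3.16e-06, adjusted p = 0.0426 with an estimated correlation). In all 11551 of 17199 genes passed (5802 rose, 5749 fell). Many changes without Rb1 had the same direction on both backgrounds, with 4442 genes rising in both where 2137 would if independent, and 4200 falling in both where 1972 would. These comparisons have no library in common but share each gene's estimated spread, which makes calls coincide, so those expected numbers are too low. In opposite directions, 419 genes rose in Rb1 knockout against WT and fell in DKO against Kdm5a knockout, and 327 did the reverse. If independent, 2118 and 1991 would have. The sizes often differed, and Myog and Ppargc1a went in opposite directions.

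A test of whether the Kdm5a effect differed between Rb1-null and Rb1-intact cells passed for 6591 of 17199 genes (3240 more positive, 3351 more negative in the absence of Rb1). Ckm (3.39 ± 0.20, limma adjusted p = 6.9e-08), Myh3 (1.78 ± 0.07), Myog (1.28 ± 0.08), Myod1 (0.59 ± 0.13) and Ppargc1a (1.21 ± 0.22) had positive differences, as did Lmod2 (4.69 ± 0.11) and Musk (4.12 ± 0.13). Sarcomere genes were positive in 39 and negative in 0 of 44 (39 and 1 adjusted over the list alone, median 1.80, camera adjusted p = 2.87e-29, adjusted p = 0.0453 with an estimated correlation), coupling and junction genes in 23 and 3 of 30 (25 and 3 adjusted over the list alone, median 1.36, camera adjusted p = 6.13e-13, adjusted p = 0.0453 with an estimated correlation) and muscle energy genes in 17 and 1 of 24 (median 1.32, camera adjusted p = 3.51e-08, adjusted p = 0.0453 with an estimated correlation). Matrix genes were negative in 40 and positive in 0 of 47 (0 and 41 adjusted over the list alone, median -1.80, camera adjusted p = 2.96e-21, adjusted p = 0.123 with an estimated correlation), such as Thbs1 (-4.98 ± 0.14) and Col5a2 (-3.08 ± 0.08). A sex effect that simply adds to the genotype effect cancels in this difference.

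Purified DKO myotubes, set against purified WT myotubes, had cell-cycle genes at high levels. E2f7 rose (9.35 ± 0.40, limma adjusted p = 0.000849, n = 2), Cdk1 rose (7.57 ± 0.28) and Mcm3 rose (5.80 ± 0.21). Of 68 replication genes 62 rose, 0 fell and 6 did not pass (68 and 0 adjusted over the list alone, median 3.14, camera adjusted p = 2.45e-25, adjusted p = 0.167 with an estimated correlation) and of 72 G2/M genes 69 rose, 0 fell and 3 did not pass (69 and 1 adjusted over the list alone, median 5.62, camera adjusted p = 1.53e-27, adjusted p = 0.721 with an estimated correlation). Muscle genes were uneven, with Myh3 falling (-1.96 ± 0.29), Ckm rising from 448 ± 21.9 to 2302 ± 5.63 (2.36 ± 0.18), Ppargc1a rising (2.10 ± 0.43), and neither Myod1 (-0.05 ± 0.51, adjusted p = 0.948) nor Myog (-0.64 ± 0.24, adjusted p = 0.0853) passing. Of 45 sarcomere genes 3 rose, 25 fell and 17 did not pass (4 and 27 adjusted over the list alone, median -1.30, camera adjusted p = 5.34e-06, adjusted p = 0.721 with an estimated correlation), with Myh8 falling from 73643 ± 6371 to 159.7 ± 5.04 (-8.84 ± 0.19). Coupling and junction genes and fatty acid oxidation genes leaned down, and p53 targets leaned up, with many members not passing. Musk fell (-5.07 ± 0.21), and Cdkn2a (3.53 ± 0.19) and the fusion gene Mymx (3.41 ± 0.25) rose. Of 30 coupling and junction genes, 0 rose, 15 fell and 15 did not pass (median -0.82, camera adjusted p = 0.00972, adjusted p = 0.737 with an estimated correlation). Of 23 fatty acid oxidation genes, 1 rose, 8 fell and 14 did not pass (median -0.55, camera adjusted p = 0.0202, adjusted p = 0.737 with an estimated correlation). Of 31 p53 targets and inhibitors, 14 rose, 2 fell and 15 did not pass (16 and 3 adjusted over the list alone, median 0.74, camera adjusted p = 0.00908, adjusted p = 0.737 with an estimated correlation). Oxidative phosphorylation genes did not pass as a list, and neither did matrix genes or the lists of other cell types. Of 78 oxidative phosphorylation genes, 3 rose, 9 fell and 66 did not pass (0 and 0 adjusted over the list alone, median -0.40, camera adjusted p = 0.0805). Of 44 matrix genes, 15 rose, 17 fell and 12 did not pass (16 and 17 adjusted over the list alone, median 0.22, camera adjusted p = 0.948, the camera test pointing down against the median). Of 15 endothelial genes, 7 rose, 1 fell and 7 did not pass (8 and 2 adjusted over the list alone, median 1.53, camera adjusted p = 0.0805), with Plvap rising (6.28 ± 0.68), and the list passed upward without WT purified replicate 1 (camera adjusted p = 0.0356) or WT purified replicate 2 (camera adjusted p = 0.0192). Of 10 macrophage and blood genes, 2 rose, 3 fell and 5 did not pass (2 and 4 adjusted over the list alone, median -0.09, camera adjusted p = 0.749), with Cd68 rising (3.76 ± 0.49). The camera adjusted p was 0.778 for smooth muscle, 0.786 for adipocyte, 0.247 for cartilage and bone, 0.764 for neural and 0.778 for epithelial genes. In all 6598 of 16670 genes passed (3500 rose, 3098 fell). The DKO purified libraries differed from each other far more than any other pair, with a median absolute log2 difference of 0.499 against 0.137 in purified WT. The count of called genes was 1983 without WT purified replicate 1, 2170 without WT purified replicate 2, 11574 without DKO purified replicate 1 and 10310 without DKO purified replicate 2. Myod1 passed as a rise without DKO purified replicate 1 (0.71, limma adjusted p = 0.00130) and as a fall without DKO purified replicate 2 (-0.81, adjusted p = 0.000917). Myog passed as a fall without DKO purified replicate 1 (-0.49, adjusted p = 0.0216) or DKO purified replicate 2 (-0.80, adjusted p = 0.00486). Myh3 did not pass without WT purified replicate 1 (adjusted p = 0.167) or replicate 2 (adjusted p = 0.143), and Ppargc1a did not without WT purified replicate 2 (adjusted p = 0.121). As lists, coupling and junction genes did not pass without DKO purified replicate 1 (camera adjusted p = 0.227) and fatty acid oxidation genes did not without DKO purified replicate 2 (camera adjusted p = 0.167) or genes that share exons (camera adjusted p = 0.102). The oxidative phosphorylation list passed downward without DKO purified replicate 1 (median -0.57, camera adjusted p = 0.00158).

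The DKO effect in purified myotubes repeated much of that in the mixed culture. Across 15917 genes tested in both, 2757 rose in both where 1152 would if the calls were independent, and 2208 fell in both where 1037 would. No library was shared, but DKO cells were female and WT cells male in both preparations, so differences of sex or embryo would recur in both. A test of the difference between the purified and mixed DKO effects passed for 4292 of 17273 genes (2012 more positive, 2280 more negative in purified myotubes). Ckm differed (3.51 ± 0.23, limma adjusted p = 1.6e-05), while Myh3 did not pass (-0.07 ± 0.21, adjusted p = 0.848) and passed without DKO purified replicate 1 (-0.32, adjusted p = 0.00571). Glycolysis genes were more positive in 14 and more negative in 1 of 22 (median 0.84, camera adjusted p = 1.67e-05, adjusted p = 0.0628 with an estimated correlation), muscle energy genes in 13 and 1 of 24 (median 0.74, camera adjusted p = 6.73e-05, adjusted p = 0.0918 with an estimated correlation), and interferon-stimulated genes in 1 and 19 of 40 (1 and 23 adjusted over the list alone, median -1.66, camera adjusted p = 1.67e-05, adjusted p = 0.0918 with an estimated correlation), such as Pygm (1.63 ± 0.13), Pkm (1.76 ± 0.19) and Ifih1 (-5.94 ± 0.26). Purification, the 24 h of recovery after it, RNA input, RNA selection, library preparation, sequencer and read length all changed together between the library types and cannot be told apart here. The count was 2471 without DKO mixed replicate 1, 2479 without DKO mixed replicate 2, 2800 without WT purified replicate 1, 8989 without DKO purified replicate 1 and 6615 without DKO purified replicate 2.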

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

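The tests of the muscle genes, of more MyoD, of a sex-dependent response and of fewer fibroblasts, and removal of genes that share exons or lie on X and Y, were chosen after the result was seen, and those of the Kdm5a knockout genes and of the purified DKO pair before.

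A test of whether the Kdm5a effect differed with and without Rb1 picked out 6591 genes. Among lists, the median difference was 1.80 for sarcomere, 1.36 for excitation-contraction coupling and neuromuscular junction, 1.32 for muscle energy metabolism, 0.53 for myogenic regulators and fusion, 0.43 for mitochondrially encoded messengers and 0.24 for the tricarboxylic acid cycle. It was -1.80 for fibroblast extracellular matrix, -1.83 for inflammatory cytokines, -0.96 for smooth muscle and myofibroblast, -0.91 for cartilage and bone, -0.71 for interferon-stimulated genes, -0.42 for endoplasmic reticulum stress and heat shock and -0.33 for autophagy and lysosome. With an estimated correlation only sarcomere (adjusted p = 0.0453), coupling and junction (adjusted p = 0.0453) and muscle energy (adjusted p = 0.0453) still passed, and matrix did not (adjusted p = 0.123). The cartilage and bone call was lost without WT mixed replicate 1 (median -0.35), Kdm5a KO mixed replicate 2 (-0.80), Rb1 KO mixed replicate 1 (-1.36), DKO mixed replicate 1 (-0.75) or genes that share exons (-0.67). The interferon call was lost without WT mixed replicate 1 (-0.50), Kdm5a KO mixed replicate 2 (-0.66), DKO mixed replicate 2 (-0.62), either Rb1 KO library or genes that share exons. The tricarboxylic acid cycle call was lost without WT mixed replicate 1 (0.22), Kdm5a KO mixed replicate 2 (0.25), Rb1 KO mixed replicate 2 (0.18) or genes that share exons (0.18). Those 3 calls were also lost without genes on X and Y (camera adjusted p = 0.0508 for each), though the medians moved little. They were then -0.91 for cartilage and bone, -0.71 for interferon-stimulated genes and 0.21 for the tricarboxylic acid cycle. The call of Kdm5c was lost without each mixed library in turn except WT mixed replicate 2, and without genes that share exons. Of the genes, Ckm differed by 3.39, Myh3 by 1.78, Myog by 1.28, Ppargc1a by 1.21, Myod1 by 0.59, Rb1 by 0.43, Kdm5b by -0.52 and Kdm5c by -0.24. Genes with large differences included Dlk1 (7.01), AW551984 (6.91), Cd36 (6.51) and Fitm1 (5.93) on the positive side and Anxa8 (-9.39), Hoxc10 (-8.23), Ifi202b (-8.03) and Rprl3 (-7.86) on the negative side. Hoxc10 had no reads in WT and Ifi202b none in DKO, so the sizes of their differences depend on the value of 1 added before the log and are not measured.

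The same kind of test, set between purified and mixed libraries, picked out 4292 genes whose DKO effect differed. Medians were 0.90 for adipocyte, 0.84 for glycolysis, 0.80 for cholesterol synthesis, 0.74 for muscle energy metabolism, 0.53 for the tricarboxylic acid cycle, 0.38 for autophagy and lysosome, 0.35 for oxidative phosphorylation and 0.32 for mitochondrial ribosomal proteins. They were -1.95 for replication-dependent histones, -1.66 for interferon-stimulated genes, -1.17 for macrophage and blood, -0.94 for mitochondrially encoded messengers, -0.93 for inflammatory cytokines and -0.40 for fibroblast extracellular matrix. The histone median is uncertain. Only 14 histone genes were measured in the purified fit against 32 in the mixed fit. The purified DKO libraries also differed on them by a median of -1.59 (replicate 2 minus replicate 1). No list passed with an estimated correlation. Without DKO purified replicate 1 the calls were lost for oxidative phosphorylation (0.04), mitochondrial ribosomal proteins (0.12), fibroblast extracellular matrix (-0.54), inflammatory cytokines (-1.02), mitochondrially encoded messengers (-0.59) and macrophage and blood (-1.17). The adipocyte call was lost without DKO purified replicate 2 (0.54), the mitochondrially encoded call without WT mixed replicate 2 (-0.88), and the macrophage and blood call without most other libraries too, such as WT mixed replicate 1 (-0.98). Of the genes, Ckm differed by 3.51, Rb1 by -0.55, Kdm5a by -1.68 and Kdm5b by -1.39. The call of Rb1 was lost without WT mixed replicate 1 (-0.55), DKO mixed replicate 2 (-0.51) or WT purified replicate 1 (-0.49). Genes with large differences included Nrxn3 (6.92), Ip6k3 (6.31), Mab21l2 (5.33) and Tbx4 (5.21), and Ifi44 (-8.22), Trpm8 (-7.42), Fap (-7.40) and Pik3cg (-7.05). Ifi44 had no reads in purified DKO, so the size of its difference is not measured either. Fap read only 2.4 and 6.4 in WT mixed and 4.9 and 4.2 in DKO purified, and Tbx4 only 7.4 and 2.5 in WT purified. The sizes of those differences rest on few reads and partly on the value of 1 added, so they are uncertain. Purification, the 24 h of recovery after it, RNA input, RNA selection, library preparation, sequencer and read length all differ between these library types, and no library separates them.

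Muscle genes stood higher in DKO than in Rb1 knockout cultures, and DKO cells were female where Rb1 knockout cells were male. An additive difference between the sexes alone is argued against by the sarcomere median of 1.80 in the test that cancels it. Myod1 also differed by 0.59 in that test. It read 4124.5 and 4120.3 in the Kdm5a knockout libraries against 5851.9 and 6886.0 in WT. A sex effect offset there by less MyoD is therefore not excluded. More Myod1 RNA at sampling is argued against by the Myod1 change of -0.03, which cannot show how much MyoD was delivered. Fewer unconverted fibroblasts in the DKO cultures could not be decided. The fibroblast matrix median was -1.74, below the mark set for this explanation, but lower expression of matrix genes per cell could give the same fall. Myog rose only 0.33 and Myod1 did not pass, beside a sarcomere median of 1.79. Neither gene can decide on cell share. Myod1 counts may include the vector's transcript, and Myog also fell far less than sarcomere genes in Rb1 knockout against WT. A response to Rb1 loss that depends on sex or on the embryo cannot be told apart from an effect of Kdm5a, as 0 Rb1 knockout libraries had Xist above 100. The pattern is therefore not assigned to Kdm5a loss within each cell.

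Many genes differed between Kdm5a knockout and WT cultures, which also differed in sex. Among genes with a known chromosome, those on X or Y made up 4.13% of the 4478 that passed (185 genes). That was near their 4.07% share of those tested, so they passed about as often as other genes. Only 655 genes on X or Y were tested, so they could not have been the bulk whatever the outcome. The share of genes that passed within 10 Mb of Kdm5a exceeded that elsewhere by only 1.52 percentage points (29.3% against 27.8%, 191 genes). Alleles carried along with the targeted locus thus left no clear excess among nearby genes. Those 191 genes could not have been the bulk either, and effects of such alleles on distant genes were not tested. Effects of sex on autosomal genes, and differences between embryos, were not tested and stay open.

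The purified DKO libraries differed from each other more than any other replicate pair. Lower read depth is argued against by a median difference of 0.47 among genes with a mean of at least 1000, where other pairs gave 0.0547 to 0.0794. Bias by RNA length is argued against by a Spearman rho of 0.04 across genes between the difference and exonic length (0.00268 in the WT pair). RNA quality and the efficiency of oligo(dT) selection were not tested. The share of reads in mt-Rnr2 was 0.109% in replicate 1 and 0.0178% in replicate 2, against 0.0623% and 0.0630% in purified WT. That of mt-Rnr1 was 0.0144% and 0.0025%, against 0.0411% and 0.0413%. A different share of myotubes could not be decided, because sarcomere genes were lower in replicate 2 by a median of -0.22 and matrix genes higher by 0.313. That is a small shift beside the whole difference. Other muscle lists were higher in replicate 2. The median was 0.316 for myogenic regulators and fusion (18 of 23 higher), 0.299 for coupling and junction (20 of 30) and 0.149 for muscle energy (15 of 23). Replication-dependent histones were lower in replicate 2 (median -1.59, 1 of 14 higher).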

How the results depend on the processing

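Removal of genes with overlapping annotation and of genes on X and Y was chosen after the data were seen, and all other alternatives were planned. Of 20371 alternative values of named genes, 19966 kept their side of the threshold, and kept their direction if they passed. Another 67 passed only under the alternative, 337 lost their call and 1 reversed. The lists kept 3600 of 3801. Changes of sign between values that did not pass were not counted as reversals. Some of these values left out a library of a group outside the comparison, which leaves the change itself as it was. Myod1 in purified DKO against WT reversed to 0.71 without DKO purified replicate 1 and was -0.81 without DKO purified replicate 2 (range -0.81 to 0.71 over libraries left out), so each DKO purified library alone sets its sign, and the cause was not tested. Counts of genes that passed, with each library left out in turn, ran from 3057 to 4697 for Kdm5a knockout against WT (3057 without Kdm5a KO mixed replicate 1). They ran from 1983 to 11574 for purified DKO against WT, with 1983 without WT purified replicate 1, 2170 without WT purified replicate 2, 11574 without DKO purified replicate 1 and 10310 without DKO purified replicate 2. For purified minus mixed they ran from 2471 to 8989, with 2471 without DKO mixed replicate 1, 2479 without DKO mixed replicate 2, 2800 without WT purified replicate 1, 8989 without DKO purified replicate 1 and 6615 without DKO purified replicate 2. Dropping a DKO purified library removes the spread of that pair from the fit, and why the other counts moved was not tested. The other comparisons stayed within 11234 to 12217 (Rb1 knockout against WT), 9834 to 11720 (DKO against WT), 5906 to 8772 (DKO against Rb1 knockout), 9881 to 12017 (DKO against Kdm5a knockout) and 4935 to 6696 (interaction). With an estimated correlation in place of the preset value fewer lists passed, and only that correlation differs between the tests. The numbers fell to 0 for Kdm5a knockout against WT, 5 for Rb1 knockout against WT and 7 for DKO against WT. They fell to 3 for DKO against Rb1 knockout, 12 for DKO against Kdm5a knockout and 3 for the interaction. For purified DKO against WT and for purified minus mixed they fell to 0. For Kdm5a knockout against WT the lists that passed ranged from 4 to 9 over libraries left out (4 without WT mixed replicate 2) and were 4 without genes with overlapping annotation, and for purified minus mixed they ranged from 8 to 15 (8 without DKO purified replicate 1), and the cause was not tested. Counts with edgeR and DESeq2 on the recovered reads were 4889 and 4297 for Kdm5a knockout against WT, 12152 and 11623 for Rb1 knockout against WT and 6538 and 6499 for purified DKO against WT.

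No pairing of libraries by replicate number was seen, with correlations of replicate differences between groups of -0.033 to 0.053. Those between mixed and purified libraries, computed after the others were seen, were -0.00275 for WT and 0.0330 for DKO. With a replicate block the counts were 4629 for Kdm5a knockout against WT, 12196 for Rb1 knockout against WT, 8067 for DKO against Rb1 knockout and 7629 for purified DKO against WT.

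Depth limits genes with few reads, and the shallowest library, DKO purified replicate 1, held 8688604 reads. Rb1 KO mixed replicate 1 held 11983750 reads, fewer than WT purified replicate 2 (14116839) or DKO purified replicate 2 (15570731). Simulated 2-fold changes were recovered for 2% of genes in the purified fit and for 69% in the mixed fit. Those simulations changed 200 genes, whereas 6598 passed in purified DKO against WT and 12237 in Rb1 knockout against WT. The adjusted threshold depends on that number, so these rates do not carry over to the comparisons. Depth, spread and the number of libraries fitted all differ between those fits, and their shares were not tested. A gene that did not pass in purified myotubes is not shown to be unchanged.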

Other observations

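Every test of this part was chosen after values had been seen. Some homeobox genes of limb and body-axis position differed between genotypes although all cells were labelled as the same fibroblasts. Hoxd13, expressed in distal limb, averaged 889 ± 33.5 in WT and 691 ± 13.2 in the Rb1 knockout against 46.4 ± 10.6 in the Kdm5a knockout and 120.4 ± 26.1 in the DKO. Hoxc10 had no reads in WT and averaged 282 ± 11.2 in the Kdm5a knockout, though its exons overlap Hoxc5 and its level is uncertain. Tbx4, a hindlimb factor, averaged 236 ± 30.97 in WT, 379.6 ± 34.8 in the Kdm5a knockout, 21.2 ± 3.27 in the Rb1 knockout and 38.6 ± 0.428 in the DKO, and Pitx1, which acts with it, averaged 42.8 ± 1.29, 378 ± 42.3, 4.07 ± 1.93 and 23.1 ± 5.88. Hoxa9 averaged 287 ± 52.3 in WT, 267 ± 27.3 in the Kdm5a knockout, 244 ± 19.2 in the Rb1 knockout and 17.9 ± 2.96 in the DKO.

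Of 33 Hox genes measured in mixed cultures, 7 rose and 5 fell in Kdm5a knockout against WT, 17 rose and 8 fell in Rb1 knockout against WT, 10 rose and 12 fell in DKO against WT, 2 rose and 25 fell in DKO against Rb1 knockout (median -1.71) and 5 rose and 14 fell in DKO against Kdm5a knockout. The share that passed, beside that of all genes, was 36.4% and 27.2%, 75.8% and 71.1%, 66.7% and 67.9%, 81.8% and 47.3%, and 57.6% and 67.2% in that order. Of 17 measured in purified myotubes, 1 rose and 10 fell in DKO against WT (64.7% passed, against 39.6% of all genes).

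The interferon-inducible gene Ifi202b averaged 290.3 ± 68.8 in the Rb1 knockout and had almost no reads elsewhere (0.533 ± 0.754 in WT, 0.350 ± 0.495 in the Kdm5a knockout, 0 in the DKO). The RNA gene Rprl3 averaged 3949 ± 295 in the Rb1 knockout against 16.1 ± 7.69 in WT, 4.51 ± 2.54 in the Kdm5a knockout and 4.47 ± 0.377 in the DKO.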
